A study of Homo sapiens with 6 samples.

How the data were processed

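Total RNA from 6 clones of KMS11, an established multiple myeloma cell line, was measured on 6 expression arrays. Per the labels, the clones were wild type, heterozygous or homozygous for a CRISPR deletion of exons 4 to 6 of CRNDE, with 2 clones of each genotype. Per the labels' protocols, a very small amount of RNA was amplified by PCR before labelling, and every sample passed the submitters' check of RNA integrity.

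The authors deposited log2 expression values from robust multi-array averaging (RMA), 1 value per transcript cluster and array, and the labels name Expression Console as the software. A transcript cluster is the group of probes that the array design assigns to 1 gene locus. Transcriptome Analysis Console is named in the submitters' processing notes. RMA corrects the background of each array, equalises the distributions of the arrays and summarises the probes. The software versions, the genome build and any filter are not given in the sources used here. The deposited table had 70523 features. Its median log2 value over all features, controls included, was 4.84 and 4.96 in wild-type clones 1 and 2. It was 4.85 and 4.89 in heterozygous clones 1 and 2, and 4.95 and 4.93 in homozygous clones 1 and 2. No centring of genes or arrays was evident in these values. All 6 sample columns of the table were matched to their samples by the labels.

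Gene symbols came from the platform annotation supplied with the table. Control features (2995) were left out, and the remaining 67528 transcript clusters were tested if their mean log2 value over all arrays was at or above the median of those means (4.84), which left 33764. Of these, 16501 carried 1 gene symbol, 1126 carried several and 16137 carried none. The Entrez identifiers of 15366 tested symbols were matched to a RefSeq gene table (GRCh38.p14), which changed 0 symbols. The RefSeq table served only for names, RNA classes and the order of genes on chromosomes. In all, 15563 genes had a tested transcript cluster. For the 288 genes with more than 1, the cluster with the highest mean was used. Of these, 0 had clusters that moved in opposite directions, each at an unadjusted p under 0.05, for homozygous minus wild type. Clusters above that p and the other comparisons were not checked for this.

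Genotypes were compared with limma 3.58.1 in R 4.3.3 on the deposited log2 values. One linear model with genotype as its only term was fitted to all 6 arrays by lmFit and moderated by eBayes, without an intensity trend or robust fitting. It had 3 residual degrees of freedom per transcript cluster, a prior of 4.23 degrees of freedom and a prior SD of 0.157. The Benjamini-Hochberg adjustment ran over the 33764 transcript clusters tested, with a threshold of 0.05. A separate model with the number of deleted alleles (0, 1 or 2) as a score had 4 residual degrees of freedom. The number of arrays limits the precision of every comparison. The replicates are clones, so each p-value measures the spread between clones, which includes differences between clones unrelated to CRNDE. An exact permutation test of 2 clones against 2 cannot give a p below 0.333 (both sides counted), so single values were tested only within the model.

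The 29 gene lists, the tests, the rule for named genes and all alternatives except those said below to have been added were fixed before the data were examined. Lists were tested with camera in limma at a preset correlation of 0.01, with 1 transcript cluster per gene, and adjusted over the 29 lists. The test was repeated with a correlation estimated from the residuals, and with fry. The lists covered interleukin 6 signalling, STAT3 targets, adhesion, plasma cell, B cell and antigen presentation genes, cell cycle phases, MYC targets, stress responses, apoptosis, p53, NF-kB and interferon genes, lipid and energy metabolism, ribosomal proteins, neighbours of CRNDE on 16q, myeloma translocation genes, chromatin complexes reported to bind CRNDE, Wnt targets, immediate early genes, histones and 4 sets of markers of other cell types. Published work on CRNDE in myeloma cells concerns interleukin 6 signalling and adhesion, so those lists are not independent of the study.

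CRNDE, its neighbours IRX5 and IRX3, and IL6R and IL6ST were always named. For each comparison, the rule took the largest rises and falls past the adjusted threshold. Because fewer than 6 transcript clusters passed, its fallback applied: the 10 largest differences in each direction among transcript clusters with 1 symbol, an unadjusted p under 0.01 and no overlap between the clones of both genotypes. Up to 4 members with the smallest p were named for each list described. Genes named outside this rule are said to have been chosen after their values were seen.

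The model was tested on simulated data for homozygous against wild-type clones with 33764 transcript clusters. It called 48% of simulated 2-fold changes and 89% of simulated 4-fold changes, with 6 false calls. On simulated values of 15563 genes that varied independently, camera called a list shifted by 0.3 and 0 of the other 28 lists. In the data, estimated correlations ran from -0.01 for p53 targets to 0.85 for amino acid response genes. Lists whose genes vary together were not simulated, so this is no check of the preset correlation for them.

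Alternatives covered the filter on dim transcript clusters, the scaling between arrays, the variance model, 1 transcript cluster per gene, the replicate number as a block, only the arrays compared, each array left out in turn, the threshold and an estimated correlation between genes. Where 1 array was left out, the lone clone of its genotype was assumed to vary like the others. Removing each array's median deviation per chromosome was added after the data were seen, as were all alternatives for the gene lists of homozygous against heterozygous clones. Covariances and overlaps expected with shared wild-type arrays came from 100 simulated sets with no effect. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.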

Results

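The series compared the transcriptomes of KMS11 clones that differed in CRNDE, a long non-coding RNA gene on chromosome 16. KMS11 is a cell line established from multiple myeloma, a cancer of plasma cells. Each genotype (wild type, heterozygous and homozygous for a deletion of exons 4 to 6) was represented by 2 clones with 1 array each. Expression is given as normalised log2 signal per transcript cluster, and differences are log2 differences between means of 2 clones with the standard error (SE) of the model. Homozygous clone 1 was closest to homozygous clone 2, while each other clone was closest to a clone of another genotype. Over the tested transcript clusters, the 2 wild-type clones had a Pearson correlation of 0.977, the heterozygous clones 0.977 and the homozygous clones 0.980. The closest pair was wild-type clone 1 with heterozygous clone 1 (0.987), followed by wild-type clone 2 with heterozygous clone 2 (0.985). These correlations are across genes, which are not independent replicates.

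CRNDE was lower in the clones carrying the deletion. Its log2 signal was 6.36 and 6.56 in the wild-type clones (mean 6.46 ± 0.14, SD, n = 2), 6.31 and 6.13 in the heterozygous clones (6.22 ± 0.13, SD, n = 2), and 6.08 and 5.90 in the homozygous clones (5.99 ± 0.13, SD, n = 2). The homozygous minus wild-type difference was -0.47 (SE 0.15, 1.39-fold), with both homozygous clones below both wild-type clones, and did not pass the threshold (limma adjusted p = 0.348). The heterozygous minus wild-type difference was -0.24 (SE 0.15, adjusted p = 1.0). The transcript cluster summarises probes over the whole CRNDE locus and not the deleted exons alone, so it is only a partial check of the genotypes. Among the neighbours on chromosome 16, IRX5 differed from wild type by -0.13 (SE 0.15) in both the homozygous and the heterozygous clones. IRX3 differed by -0.29 (SE 0.20) in homozygous and 0.19 (SE 0.20) in heterozygous clones. Neither gene passed the threshold.

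The comparison of homozygous with wild-type clones asks how loss of the deleted exons on both alleles relates to expression. IL6R, which encodes the ligand-binding chain of the interleukin 6 receptor, had a signal of 8.51 and 9.07 in the wild-type clones against 6.89 and 6.86 in the homozygous clones, a difference of -1.92 (SE 0.53, 3.77-fold). IL6ST, which encodes the signal-transducing chain of the same receptor, differed by 0.24 (SE 0.18, adjusted p = 0.731). Other large differences towards lower signal were BMP6, a secreted bone morphogenetic protein (-1.72, SE 0.45), ATP8B2, a subunit of a phospholipid flippase (-1.38, SE 0.31), and CDH2, which encodes N-cadherin (-1.21, SE 0.14). CD38, a plasma cell surface enzyme that is a target of antibody therapy in myeloma, differed by -0.90 (SE 0.12). DSEL (-1.09), SOBP (-1.02), the magnesium transporter gene SLC41A1 (-0.98), ZSWIM6 (-0.95) and the kinase gene HIPK2 (-0.92) completed this group. Without homozygous clone 1, ATP8B2 was at -0.86 and HIPK2 at -0.52. Among genes that met the rule, the largest difference towards higher signal was that of HLA-DQA1, a chain of an MHC class II molecule (2.44, SE 0.64). Next were CTSS, the protease that trims the invariant chain of class II molecules (2.06, SE 0.46), and CDH17, a cadherin (1.79, SE 0.37). The small nucleolar RNA genes SNORA54 (1.63), SNORA24 (1.5), SNORA12 (1.37) and SNORD15A (1.32) followed, with MIR4659A (1.32), LINC00342 (1.30) and the orphan receptor gene GPR52 (1.29). Without wild-type clone 1, SNORD15A was at 0.79. Small nucleolar RNAs and class II genes have near-identical copies or several haplotypes on the array, so signal can be shared between them.

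None of these genes passed the adjusted threshold. In limma, 0 of 33764 transcript clusters did. The lowest adjusted p was 0.0567, for a transcript cluster without a gene symbol (TC16001901.hg.1, chosen after its values were seen). Its signal was 4.36 and 4.09 in the wild-type clones, 6.73 and 6.16 in the heterozygous clones, and 7.24 and 7.08 in the homozygous clones, a homozygous minus wild-type difference of 2.94 (SE 0.21). For the genes just named, the adjusted p was 0.299 for IL6R, 0.283 for BMP6 and HLA-DQA1, 0.232 for CTSS, 0.197 for CD38 and 0.161 for CDH2. At an unadjusted p under 0.05 there were 3538 transcript clusters, 2610 higher and 928 lower in homozygous clones, where 1688.2 would be expected on average by chance. Transcript clusters vary together, so such a count can lie far from that average by chance, and the excess was not tested. For the number of deleted alleles, other assignments of the arrays gave from 364 to 5095 at this p. The higher share was 73.8% on the deposited scale, 56.4% after each array was centred on its median and 56% after repeated quantile normalisation. The clones of both genotypes did not overlap in 37.9% of transcript clusters, against 33.3% by chance. The count of calls depended on the arrays used: 27 transcript clusters passed when only the 4 homozygous and wild-type arrays were fitted or when either heterozygous clone was left out, among them HLA-DQA1, CTSS, IL6R and BMP6. Of these 27, 20 carried no symbol or several. HLA-DQA1 was present with more than 1 cluster, at differences of 1.59, 2.12 and 2.44. The value of 2.12 came from 2 clusters with identical values on every array. Without homozygous clone 2, 7 passed, all lower in homozygous clone 1, of which 1 had a symbol (UBE3A, 3.69 in that clone against 7.64 in homozygous clone 2).

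**Figure D1:**
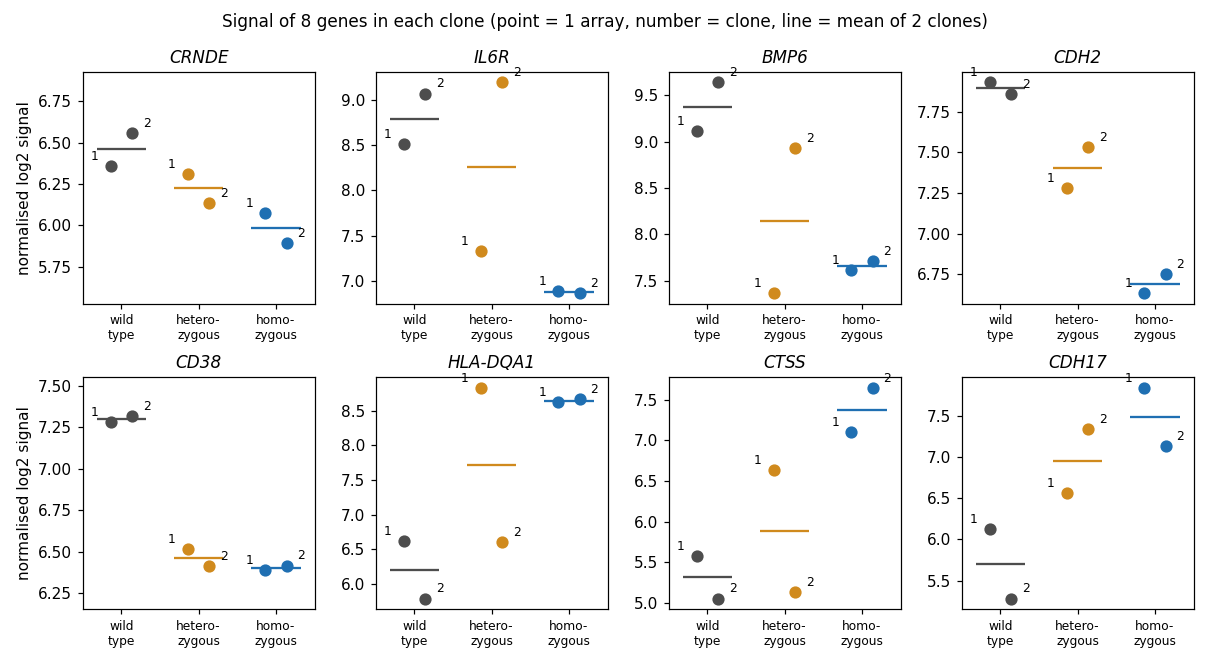
Normalised log2 signal (vertical axis) of 8 genes in each clone, with 1 point per array, the clone number beside it and a line at the mean of 2 clones. IL6R lies at 6.89 and 6.86 in the homozygous clones, while heterozygous clone 1 (7.33) and heterozygous clone 2 (9.19) lie far apart.

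Gene lists were compared next. In the homozygous clones 6 of 29 lists shifted against wild type with the preset correlation in camera, 3 up and 3 down. With an estimated correlation 0 were called, and the adjusted p was 0.880 for each of the 6. Fry, which tests a list without comparing it with other genes, called 0 lists (lowest adjusted p = 0.429, or 0.133 for change in either direction). The MHC class II list shifted most, with a median of 0.54, 13 of 14 members higher and 11 of them without overlap between clones (adjusted p = 1.05e-07). Adjusted over the list alone, 5 of its members passed, against 0 over all transcript clusters. They included CTSS, HLA-DQA1 and both chains of the peptide-exchange factor, HLA-DMA (1.07) and HLA-DMB (0.59). The list median was already high in heterozygous clone 1 and low in heterozygous clone 2 (0.27 and -0.34 relative to the mean of all arrays).

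Oxidative phosphorylation genes shifted up by a median of 0.18, with 27 of 30 members higher (adjusted p = 9.33e-05). The respiratory chain genes NDUFB5 (0.56), NDUFA9 (0.52), COX5B (0.46) and NDUFV2 (0.45) had the smallest p, but none passed over the list alone. Cytosolic ribosomal proteins shifted up by a median of 0.16, with 27 of 28 members higher (adjusted p = 9.33e-05), for example RPL24 (0.32), RPS14 (0.32) and RPL29 (0.26). Without homozygous clone 1 these medians were 0.10 for both lists. Without homozygous clone 2 they were 0.33 and 0.26.

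MYC targets and ribosome biogenesis genes shifted down by a median of -0.18, with 22 of 31 members lower (adjusted p = 0.00167). CAD, an enzyme of pyrimidine synthesis (-0.86), passed over the list alone (adjusted p = 0.0372), and ODC1, an enzyme of polyamine synthesis (-0.50), did not. This call was lost without wild-type clone 1 (median -0.05, adjusted p = 0.625). All 15 tested canonical Wnt targets were lower, with a median of -0.19 (adjusted p = 0.00183), among them ZNRF3 (-0.45), APCDD1 (-0.31) and AXIN2 (-0.23), which all encode inhibitors of the pathway. Without wild-type clone 2 the median was -0.07. Myeloma genes tied to the t(4;14) translocation or to MAF were lower in 15 of 16 cases, with a median of -0.14 (adjusted p = 0.0494). NUAK1 (-0.74) and CCND2 (-0.35) were lower, and SLC2A13 (0.33) was higher, with NUAK1 at -0.38 without homozygous clone 1. This call was lost under centring (median -0.18, adjusted p = 0.0801), quantile normalisation (-0.18, 0.0834) and robust variances (-0.14, 0.0581), and without wild-type clone 1 (-0.22, 0.0800), although the median was as large or larger there. It was also lost without wild-type clone 2 (-0.09, 0.129) or homozygous clone 1 (-0.06, 0.635). Over this comparison, 17 of 45 single-gene differences became over 1.5 times smaller or reversed without 1 of the clones.

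**Figure D2:**
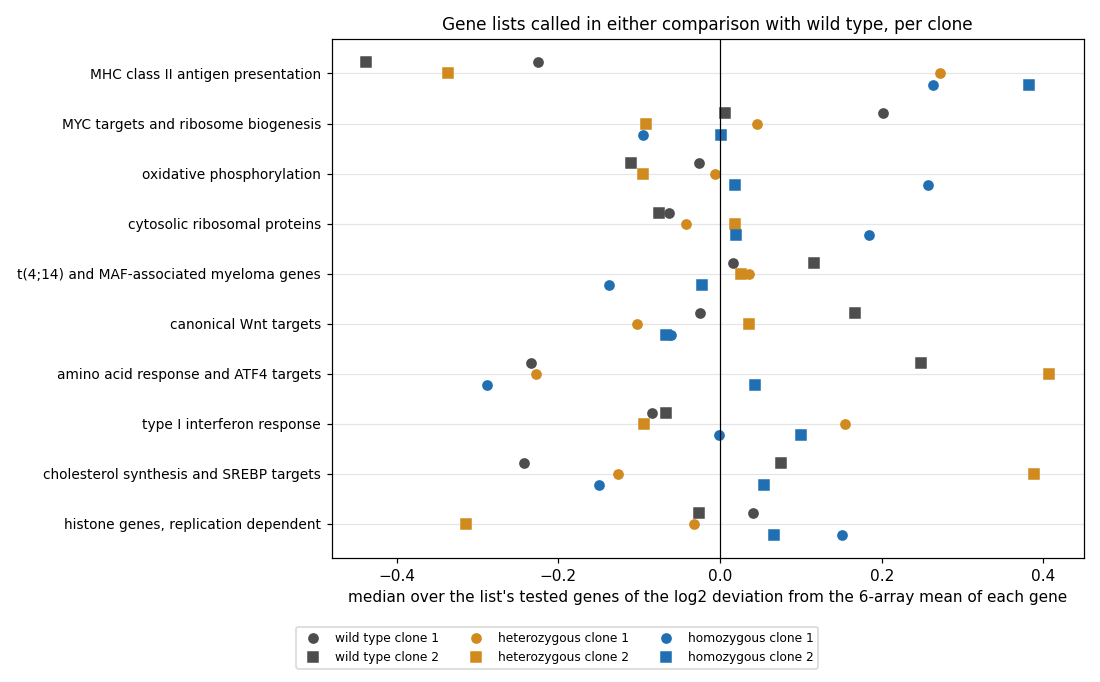
Median over each list's tested genes of the log2 deviation from the mean of all 6 arrays (horizontal axis), per clone, for the 10 lists called in either comparison with wild type. The MHC class II medians of the homozygous clones (0.26 and 0.38) lie close to that of heterozygous clone 1 (0.27), and heterozygous clone 2 (-0.34) lies with the wild-type clones (-0.22 and -0.44).

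The interleukin 6 and adhesion lists, which the study's own interest makes dependent evidence, were not called. Of 16 interleukin 6 signalling genes, 9 were lower and the median was -0.04 (adjusted p = 0.399), with SHC1 at -0.32, PTPN11 at -0.31 and GAB1 at 0.42. Of 36 adhesion genes, 27 were lower and the median was -0.10 (adjusted p = 0.125). CDH2 passed over the list alone (adjusted p = 0.00189), while SDC1, which encodes the plasma cell marker syndecan, was at -0.59, ITGB3 at -0.44 and ITGAL at 0.82. The plasma cell list had a median of -0.04 (adjusted p = 0.399), although CD38 passed over the list alone (adjusted p = 0.00370), with IRF4 at -0.39 and JCHAIN at 0.62. The median was -0.02 for STAT3 targets (adjusted p = 0.929), whose mean and test pointed up (mean 0.06). It was -0.08 for the unfolded protein response and -0.05 for glycolysis (both adjusted p = 0.125).

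At an adjusted p of 0.399, the medians were -0.07 for the B cell programme, -0.04 for DNA replication genes, 0.12 for mitotic genes, -0.12 for amino acid response genes, 0.04 for apoptosis regulators, 0.17 for interferon genes, 0.04 for cholesterol synthesis, -0.06 for genes near CRNDE on 16q, -0.05 for immediate early genes and 0.09 for histones. Targets of p53 (0.02, adjusted p = 0.970) and NF-kB (0.02, 0.564) did not shift. Subunits of the PRC2 and CoREST complexes had a median of 0.02 (0.859), with mean and test pointing down. Markers of other cell types were not called: T and NK cells (-0.06, adjusted p = 0.460), myeloid cells (-0.04, 0.848), stroma and endothelium (-0.08, 0.399), and erythroid cells and megakaryocytes (-0.03, 0.859, mean 0.07). These 4 marker lists all had their highest median in wild-type clone 2, between 0.13 and 0.20, where the Wnt targets also had theirs (0.17).

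The comparison of heterozygous with wild-type clones asks about loss of the exons on 1 allele. Among genes that met the rule, CR2, the B cell complement receptor, had the largest difference towards higher signal (1.41, SE 0.24). HLA-DQA1 differed by more (1.51) but did not meet the rule. After CR2 came ACSM3 (1.25), SYT11 (1.24), ZC3H6 (0.93), PCBD1 (0.87), GPR52 (0.81) and CD48 (0.80). The glucose transporter gene SLC2A12 (0.79), ATF7IP2 (0.78) and the potassium channel gene KCNN3 (0.76) followed. CD38 was lower by nearly as much as in the homozygous clones (-0.84, SE 0.12). MIR5047 (-0.92), MIR221 (-0.88), the necroptosis effector gene MLKL (-0.83), SNTB2 (-0.79), SNORD88C (-0.58), LY6G5B (-0.56), ADM5 (-0.51) and MIR3661 (-0.47) were also lower, and no other gene met the rule in that direction. IL6R differed by -0.53 (SE 0.53) and stood at 7.33 in clone 1 and 9.19 in clone 2. Without heterozygous clone 1 its difference was 0.40. IL6ST differed by 0.16 (SE 0.18).

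In limma 0 of 33764 transcript clusters passed for heterozygous against wild type (lowest adjusted p = 0.199, and 1.0 for each gene just named). The lowest was that of the unnamed TC04002413.hg.1 (chosen after its values were seen), which differed by 1.41 (SE 0.12). At an unadjusted p under 0.05 there were 844, fewer than the 1688.2 expected on average by chance, with 525 higher and 319 lower. The clones of both genotypes did not overlap in 24.9% of transcript clusters, against 33.3% by chance. Wild-type and heterozygous clones of the same number deviated alike (correlation 0.463), which the model leaves out and which can lower both values. The low count is therefore no evidence against an effect. Without heterozygous clone 2, 3 transcript clusters passed, the unnamed TC16001901.hg.1 and 2 clusters of HLA-DQA1. Adjusted over the list alone, CR2 passed in the B cell list (adjusted p = 0.0104) and CD38 in the plasma cell list (adjusted p = 0.00585).

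With the preset correlation 7 of 29 lists shifted in the heterozygous clones, 4 up and 3 down, and with an estimated correlation 0 did (adjusted p = 0.874 for each). Cholesterol synthesis genes shifted up by a median of 0.23, with 24 of 27 higher (adjusted p = 1.89e-07), for example STARD4 (0.53), TM7SF2 (0.44) and MSMO1 (0.40). Amino acid response genes had a median of 0.18 with 21 of 29 higher (adjusted p = 0.0342), for example DDIT4 (0.55) and DDIT3 (0.41). Histone genes shifted down by a median of -0.27, with 9 of 10 lower (adjusted p = 5.13e-05), for example H2BC11 (-0.49) and H1-4 (-0.39). MYC targets had a median of -0.13 with 29 of 31 lower (adjusted p = 4.02e-04), for example ODC1 (-0.52) and SRM (-0.31). The MHC class II list had a median of 0.29 with 12 of 14 higher (adjusted p = 5.13e-05), for example HLA-DQA1 (1.51) and HLA-DMA (0.78). Interferon genes had a median of 0.13 with 18 of 23 higher (adjusted p = 0.0342), for example IFI6 (0.56) and IFI16 (0.42). Wnt targets had a median of -0.09 with 14 of 15 lower (adjusted p = 0.0342).

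Each of these 7 calls rested on single clones. Without heterozygous clone 2 the median was -0.01 for cholesterol synthesis, -0.23 for amino acid response genes, 0.02 for MYC targets and -0.10 for histones. Without heterozygous clone 1 it was -0.10 for MHC class II, -0.06 for interferon genes and -0.05 for Wnt targets. Without wild-type clone 1 every call except that of MHC class II was lost. The medians of MYC targets and amino acid response genes turned to 0.0022 and -0.13 there. Those of cholesterol synthesis and histones were 0.09 and -0.19. The medians of interferon genes (0.13) and Wnt targets (-0.18) were no smaller than with all clones. Without wild-type clone 2 the calls of MHC class II, interferon genes and Wnt targets were lost. Their medians there were 0.17, 0.11 and -0.01, and that of interferon genes was close to its value with all clones. The interferon and amino acid response calls were also lost under centring (camera adjusted p = 0.0526 for both, medians 0.14 and 0.19). Under quantile normalisation they were lost too (0.0579 and 0.115, medians 0.14 and 0.16). These medians were close to those on the deposited scale. The filter at the 75th percentile also lost both calls (0.245 and 0.165, medians 0.13 and 0.18). The interferon call was lost with no filter (0.0665, median 0.08), and the amino acid response call with robust variances (0.0613, median 0.18). Single genes depended on clones too, and 25 of 51 differences became over 1.5 times smaller or reversed without 1 of them. Without wild-type clone 1 DDIT4 was at 0.0012. Without heterozygous clone 1 IFI6 was at 0.05, HLA-DQA1 at 0.39 and HLA-DMA at 0.41. Without heterozygous clone 2 STARD4 was at 0.15 and MSMO1 at 0.09.

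Homozygous and heterozygous clones were also compared directly. Among genes that met the rule, the largest differences towards higher signal in homozygous clones were mostly in short RNA genes. These were SNORA21 (1.27, SE 0.25), RNA5SP108 (1.17), SNORA50C (1.11), MIR3143 (1.07), RNU6-3 (0.91) and another U6 gene (0.96). The others were YAE1 (1.0), RIMS2 (0.94), APPAT (0.91) and LINC00342 (0.89). CTSS (1.49) and SNORA24 (1.30) differed by more but did not meet the rule. Those towards lower signal included PIK3CG, a catalytic subunit of phosphoinositide 3-kinase (-1.32, SE 0.36), CR2 (-1.27, SE 0.24), the adhesion molecule gene NRCAM (-1.17), MTMR10 (-1.08), DSEL (-0.99), DMXL2 (-0.98), the Wnt ligand gene WNT5A (-0.97), KCNN3 (-0.94), TMEM47 (-0.94) and the kinase gene PRKCB (-0.89). IL6R differed by -1.39 (SE 0.53), IRX3 by -0.48 (SE 0.20) and CRNDE by -0.24 (SE 0.15). IL6R was at -0.45 without heterozygous clone 2 and -2.32 without heterozygous clone 1, and PIK3CG at -0.67 without homozygous clone 1. Of 65 single-gene differences, 36 became over 1.5 times smaller or reversed without 1 of the clones. In limma 0 transcript clusters passed (adjusted p = 0.421 to 0.545 for the genes chosen by the rule, and the lowest 0.138 for the unnamed TC08002058.hg.1, chosen after its values were seen, at 1.91, SE 0.16). At an unadjusted p under 0.05 there were 2343, 1615 higher and 728 lower, a higher share of 68.9% that became 46.2% under centring and 52% under quantile normalisation. Without homozygous clone 2, 7 passed, with UBE3A again the only one with a symbol.

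A graded change with the number of deleted alleles was tested last. The slope of CRNDE was -0.24 per allele (adjusted p = 0.268), that of IL6R was -0.96 (0.265) and that of CDH2 was -0.60 (0.126). In limma 0 transcript clusters passed for the slope (lowest adjusted p = 0.0698), and the unnamed cluster with that p, identified as TC10002194.hg.1 (chosen after its value was seen), had a slope of 0.65 (SE 0.05). There were 3887 at an unadjusted p under 0.05, 2820 with positive and 1067 with negative slopes, a positive share of 72.5% that became 56.5% under centring and 54.7% under quantile normalisation.

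Both deletion genotypes were compared with the same wild-type arrays, which makes their differences covary without any effect. The covariance of the homozygous and heterozygous differences from wild type was 0.0246, against 0.0239 (SD 7.77e-04, 100 simulated sets) with no effect, a difference of 7.01e-04. The correlation was 0.489 against 0.5 simulated. At an unadjusted p under 0.05, 301 transcript clusters were higher in both (2610 and 525 in each, 40.6 if independent) and 72 were lower in both (928 and 319, 8.77 if independent). In the simulated sets with no effect, 266 were higher in both on average (SD 14.7, highest 305) and 262 lower in both (SD 16.3). Relative to independence the overlap was 7.42-fold for higher and 8.21-fold for lower signal, against 10.7-fold and 10.6-fold in the simulated sets. On average those sets held 916 and 916 transcript clusters higher and 915 and 913 lower in each comparison, unlike the data. Both the overlap and its ratio depend on these numbers, so neither is compared like for like. Transcript clusters were also simulated as independent of each other, so the simulated SDs may be too small. The 2 wild-type arrays cannot be divided into separate sets of at least 2 each, so all or part of the excess over independence may come from the shared controls, and it is no evidence of a shared effect. Without wild-type clone 1 the covariance was 0.0665.

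Differences between clones also followed chromosomes. The median deviation of genes on chromosome 4 was -0.16 in wild-type clone 2 and -0.07 in heterozygous clone 2, against 0.05 in wild-type clone 1, 0.07 in heterozygous clone 1, and 0.04 and 0.05 in the homozygous clones. Chromosomes 8 and 12 had medians of -0.14 and -0.11 in wild-type clone 2. On chromosomes 4, 8 and 12, 12.5% of transcript clusters were higher in homozygous than wild-type clones at an unadjusted p under 0.05, against 7.12% elsewhere. These chromosomes were chosen because wild-type clone 2 was low on them, so a larger share there follows from the choice and is no separate evidence. On the other chromosomes the share ran from 2.20% (chromosome 21) to 10.6% (chromosome 10).

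**Figure D3:**
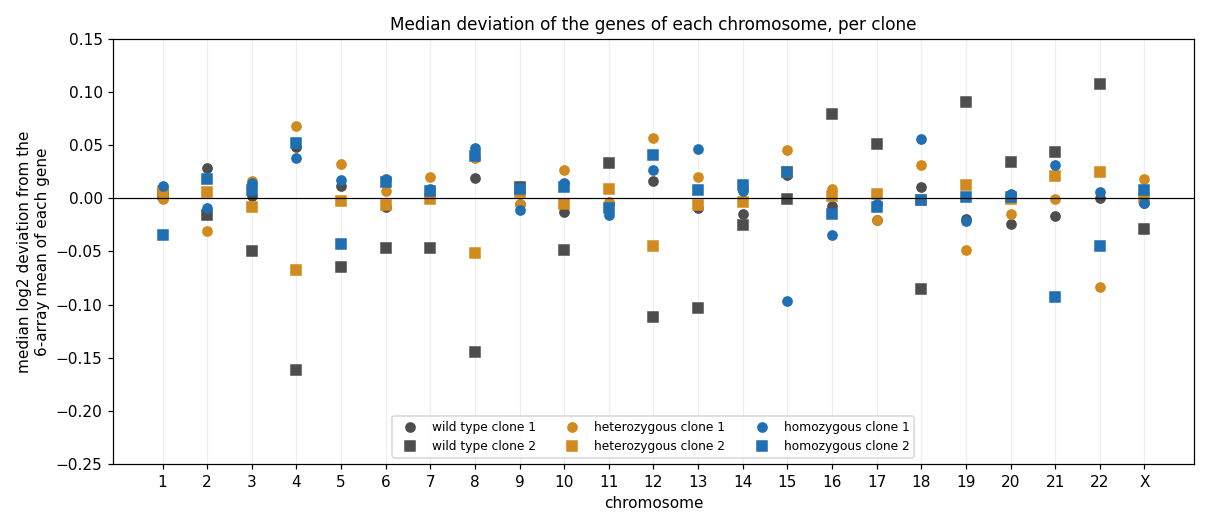
Median log2 deviation from the mean of all 6 arrays (vertical axis) of the tested genes on each chromosome (horizontal axis), with 1 point per clone. Wild-type clone 2 lies below all other clones on chromosomes 4 (-0.16), 8 (-0.14) and 12 (-0.11), and homozygous clone 1 does on chromosome 15 (-0.10). Wild-type clone 2 lies above all other clones on chromosomes 16 (0.08), 19 (0.09) and 22 (0.11), for example.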

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

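The removal of chromosome medians, and all alternatives for the gene lists of homozygous against heterozygous clones, were chosen after the data were seen. CRNDE kept its direction and stayed short of the threshold in all 16 settings run, from -0.57 to -0.37 for homozygous minus wild type (adjusted p from 0.225 to 0.929) and from -0.34 to -0.14 for heterozygous minus wild type. It lies below the 75th percentile of signal, so that filter gave it no value. The gene lists already use 1 transcript cluster per gene, so that alternative applied to no list. Each scaling alternative moved the median of all transcript clusters by less than 0.1.

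The count of transcript clusters for homozygous against wild type was 0, but 1 with robust variances and 27 with only the 4 arrays compared, where fewer samples gave another estimate of the spread. Leaving out each array gave 0 to 27. At an unadjusted p under 0.05 and at least 2-fold, 236 differed (66 with 1 symbol), with 31 for heterozygous against wild type, 156 for homozygous against heterozygous and 234 for the alleles. Leaving out each array gave 0 to 3, 0 to 7 and 0 for those. Lists called numbered 0 in each of the 3 comparisons with an estimated correlation, and 5 to 9, 2 to 8 and 3 to 12 without single arrays. The covariance ran from 0.0128 to 0.0665 without single arrays, where a lone wild-type clone carries more chance covariance by construction. Otherwise the cause was not tested.

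With the replicate number as a block, 4 transcript clusters passed for homozygous and 1 for heterozygous against wild type, all without a single symbol, with TC16001901.hg.1 among them in both and also the 1 with robust variances. Same-numbered deviations correlated at 0.463 (wild type and heterozygous), 0.0529 (wild type and homozygous) and 0.138 (heterozygous and homozygous). Wild-type and heterozygous clones of the same number were the 2 closest pairs (0.987 and 0.985), and the median of amino acid response genes was lower in clone 1 than in clone 2 of every genotype. The labels name no batch or day that a number marks, and the correlation of wild type and homozygous clones is near 0, so the numbers were not taken to pair the clones. The block moved no other count of calls by over 1.5 times.

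Without single arrays, these single genes reversed. For homozygous minus wild type IRX5 ran from -0.278 to 0.0179. For heterozygous minus wild type IRX5 ran from -0.274 to 0.0220, IL6R from -1.46 to 0.40, DDIT3 from -0.14 to 0.96 and MTHFD2 from -0.0587 to 0.57. For homozygous minus heterozygous IRX5 ran from -0.0595 to 0.0513 (0.0260 with chromosome medians removed), IL6ST from -0.13 to 0.29 and HLA-DRB1 from -0.13 to 1.77. List medians of heterozygous minus wild type ran from -0.10 to 0.46 for MHC class II, -0.25 to 0.0196 for MYC targets, -0.23 to 0.48 for amino acid response, -0.0626 to 0.25 for interferon and -0.00644 to 0.44 for cholesterol synthesis. Those of homozygous minus heterozygous ran from -0.0437 to 0.65 for MHC class II, -0.57 to 0.14 for amino acid response, -0.42 to 0.0737 for cholesterol synthesis and -0.14 to 0.0083 for glycolysis, and the 16q median was 0.0026 with no filter. In all, 2677 of 2700 settings of 161 single-gene results kept direction and side of the threshold, 12 passed it and 11 reversed. As 0 of these results passed in the main fit, keeping the side means only that they still did not pass. The 12 passes were of HLA-DQA1, CTSS, IL6R and BMP6. They came from the fit of only the arrays compared and from leaving out either heterozygous clone, which amounts to the same fit. Of 391 settings of 23 list medians, 317 kept both, 62 lost the call and 12 reversed. Background features had medians of 2.89 to 3.15 on the arrays, against 6.26 to 6.36 for the tested transcript clusters.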

Other observations

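Tests of the chromosome pattern, of the recovery of short RNA and of a mislabelled clone were chosen only after the results were seen. Homozygous and heterozygous clones also differed in gene lists. With the preset correlation in camera 10 of 29 lists shifted, 4 up and 6 down in the homozygous clones, and 0 did with an estimated correlation (limma adjusted p from 0.782 to 0.794). Histone genes were higher in 10 of 10 cases, with a median of 0.28 (adjusted p = 2.50e-05), for example H1-4 (0.49) and H2BC9 (0.45). Oxidative phosphorylation (median 0.19, adjusted p = 5.42e-04), MHC class II (0.30, 0.00107) and ribosomal proteins (0.13, 0.00298) also shifted up. Unfolded protein response genes shifted down, with 24 of 30 lower and a median of -0.15 (adjusted p = 3.24e-04), for example the chaperone gene HYOU1 (-0.54) and PDIA4 (-0.49). Amino acid response genes (-0.26, 0.00231), cholesterol synthesis (-0.20, 0.00231), glycolysis (-0.14, 0.00498), myeloma genes of t(4;14) or MAF (-0.10, 0.0104) and 16q genes (-0.04, 0.0155) shifted down too. The amino acid response and cholesterol calls were lost with repeated quantile normalisation (adjusted p = 0.0716 for both, over all alternatives from 1.37e-17 to 0.794 and from 4.48e-11 to 0.782), although their medians were no smaller there (-0.32 and -0.21). The 16q call was lost with chromosome medians removed (median -0.0067, adjusted p = 0.0800, over all alternatives from 0.00285 to 0.782). Adjusted over the list alone, P4HA1 in the glycolysis list (-0.67, adjusted p = 0.0473), CDH2 in the adhesion list (-0.72, 0.0494) and CR2 in the B cell list (-1.27, 0.0195) passed. All of these list calls except that of histones were lost without at least 1 clone. Without heterozygous clone 2 the medians were 0.00 or reversed for the unfolded protein response (-0.00152), amino acid response (0.14), cholesterol synthesis (0.07) and MHC class II (-0.04).

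Some classes of short RNA had higher medians in the homozygous clones, and no test of the classes was run. The 113 small nucleolar RNA genes had a median homozygous minus wild-type difference of 0.25 (bootstrap SE over genes, not clones, 0.04), with 92 higher (81.4%), and deviations of -0.01 and -0.16 in the wild-type clones, -0.09 and -0.20 in the heterozygous clones, and 0.37 and 0.07 in the homozygous clones. The median was 0.21 with centred arrays and 0.20 with repeated quantile normalisation. The 97 genes with RNU symbols, of small nuclear RNAs and their copies, had a median of 0.67, with 95 higher. The 18 genes annotated as small nuclear RNA had a median of 0.04 with 11 higher, which became -0.0068 with centred arrays and -0.0479 with repeated quantile normalisation. The 427 microRNA genes had a median of -7.7e-04. Medians were higher for the 14 genes with SCARNA symbols (0.51, 12 higher), 24 with RNY symbols (0.26, 22 higher) and 214 with RNA5S symbols (0.12, 155 higher). Members of these families share near-identical sequence, so single members are uncertain. The 453 genes annotated as pseudogenes also had a higher median (0.15, 72.8% higher), so the rise was not limited to genes annotated as short RNA. How many of them are copies of the short RNAs above was not counted. Protein-coding genes had a median of -0.03, with 41.6% higher.

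For small nucleolar RNAs, chromosome-wide differences between clones were argued against, since the median was 0.266 with chromosome medians removed. Transcription of their host genes stayed open, because the host median of 0.0234 rests on 4 genes. Recovery of short RNA in the preparations may also differ. The microRNA median of -7.7e-04 does not settle it, since each clone had 1 preparation and microRNA clusters also detect longer transcripts. An effect of the genotype is likewise open and untested beyond the comparison itself.

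For chromosomes 4, 8 and 12, the mean of their medians differed by 0.167 between the wild-type clones, and genotype means differed by 0.0965 at most. These chromosomes were chosen because wild-type clone 2 stood apart on them, so this comparison is no test of an effect of genotype, which stays open. An array-wide trend with base composition was tested on chromosomes 13 and 18, which are as rich in A and T. In heterozygous clone 2 their mean was -0.00398 against -0.0549 for chromosomes 4, 8 and 12, which argues against it there. In wild-type clone 2 it was -0.0942 against -0.139, and background features rich in G and C stood 0.297 above poor ones on that array, so the trend cannot be told apart from a chromosomal difference. Wild-type clone 2 also stood high on chromosomes 22 (0.107), 19 (0.091) and 16 (0.079), where heterozygous clone 1 was at -0.083, -0.048 and 0.009. In heterozygous clone 1, background features rich in G and C differed from poor ones by -0.189. Gains or losses in single clones could give this pattern, but DNA was not measured here. In all, 20 of 23 chromosomes varied more between arrays than all 1000 random gene sets. An array-wide trend could also move many chromosomes, so this count does not tell it apart from gains or losses.

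For IL6R, a change of the whole surrounding region was argued against. The 40 nearest tested genes had a median homozygous minus wild-type difference of -0.055 (bootstrap SE over genes 0.025), with 26 of them lower. The lowest of these neighbours was ATP8B2 at -1.38, which is also among the largest falls named above. A median over 40 genes cannot exclude a change limited to a few genes near IL6R. Heterozygous clone 1 resembled the homozygous clones at IL6R, BMP6 and HLA-DQA1, and lay nearer to them than to wild type for 14 of the 20 genes named for that comparison, against 3 for heterozygous clone 2. Over all 310 genes eligible for that choice it did so for 112, against 65, with a median position of 0.391 between the means of wild type (0) and homozygous clones (1). A mislabelled homozygous clone could explain the resemblance at the named genes. Against it, heterozygous clone 1 correlated best with wild-type clone 1 (0.987), and its CRNDE signal stood 0.327 above the homozygous mean. None of these values rules it out. Homozygous clone 2 also correlated better with wild-type clone 1 (0.983) than with homozygous clone 1 (0.980). Over 682 genes chosen from homozygous clone 1 and wild type alone, the median position was 0.405 for homozygous clone 2 and 0.321 for heterozygous clone 1. Heterozygous clone 2 was at 0.0895 there. Over 192 chosen from homozygous clone 2 it was 0.789 for homozygous clone 1 and 0.478 for heterozygous clone 1. The CRNDE difference was 1.81 times its SE, in a cluster not limited to the deleted exons. Genes chosen from 1 homozygous clone favour values that are extreme in that clone, so the other clone tends to fall short of 1. The homozygous clones did not lie further apart than other pairs. The median absolute difference between clones was 0.136 for them, against 0.152 for heterozygous and 0.205 for wild-type clones. With 1 array per clone, a mislabelled clone and ordinary variation between clones cannot be told apart.

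For the number of deleted alleles, the real assignment gave 0 calls, so all 45 ways of assigning 0, 1 and 2 alleles to the arrays give at least as many whatever the data, and this count says nothing about chance. The highest of the others was 18. At an unadjusted p under 0.05, 5 of 45 gave at least the 3887 of the real one, with 5095 at most in the others, so chance cannot be excluded for that count. Of the other assignments, 18 calls came from one that scored wild-type clone 2 and heterozygous clone 2 as 0, wild-type clone 1 and heterozygous clone 1 as 1 and both homozygous clones as 2 (5095 at the unadjusted p). Another with a different scoring also gave 18 (3745 at the unadjusted p), with wild-type clone 1 and homozygous clone 1 as 0 and wild-type clone 2 and heterozygous clone 2 as 2. Both were picked out for their counts, so they point to a structure of the samples without showing which.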
